A study of Drosophila melanogaster with 4 samples.

How the data were processed

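The series measured monomethylation of lysine 4 of histone H3 (H3K4me1) by chromatin immunoprecipitation followed by sequencing (ChIP-seq), in nuclei of wild-type Oregon-R Drosophila melanogaster third-instar larvae. Per the labels, there were 4 samples: 2 ChIP samples made with a single lot of one antibody (replicates 1 and 2) and 2 input samples of sheared chromatin without immunoprecipitation (replicates 1 and 2). Each input served as the background for the ChIP list of the same replicate number, per the labels. The inputs have no region list of their own among the data used here, so no comparison of ChIP with input values could be computed. The labels call the replicates separate samples without saying that they came from separate cultures, so any spread or p-value between them may be technical.

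Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Coordinates are on FlyBase release 5 of the genome, per the file headers, which also give the length of each of 14 sequences. The region caller, its threshold, its smoothing and its filters are not given in the sources used here. The deposited data were 3 lists of regions: 1 for each ChIP sample and 1 for the whole series, called the combined list here. How the combined list was made, from pooled reads or from the replicate lists, is not given in the sources used here. Each region has a start, an end and 1 deposited score, which is the authors' own value. The score was above 0 in regions named enriched and below 0 in regions named depleted. No file states its scale. Among the 50 most repeated scores of each list, the differences from the most repeated one fell on log2 ratios of whole numbers up to 60, within 1e-06, for 67.3% of 49 scores in replicate 1, 79.6% in replicate 2 and 34.7% in the combined list. Under a natural or base-10 logarithm 0% did, and after adding an arbitrary offset at most 0.0816% did on average. The scale was therefore taken to be log2 from the values. The plan fixed before the data were examined had foreseen a log transformation, which was left out because the score was taken to be on a log scale already, with 0 separating regions named enriched from those named depleted. Scores were compared within a list or as ranks, apart from the lowest enriched scores of the replicates, which are given side by side as deposited.

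Enriched regions entered all comparisons, and depleted regions were set aside. Overlap meant at least 1 shared base. The share of regions overlapping the other replicate, and the shared bases as a percentage of the union of bases, were tested against 1000 circular shifts of one list within each chromosome (one-sided, smallest possible p 0.001), which keep region widths and spacing. Scores and widths of overlapping and non-overlapping regions were compared by the difference of medians with a two-sided permutation test of 100000 resamples (smallest possible p 1e-05). Rank correlation of scores used regions that overlapped exactly 1 region of the other list and were overlapped by that region alone, also with 100000 resamples. These tests run across regions, which are not independent replicates. With 2 samples in 1 group no exact permutation test over samples can reach 0.05, so values per list are given with the mean and SD over the 2 replicates. Shares of regions carry 95% Wilson intervals, which cover counting error only. The number of reads behind each list is unknown, since the lists hold no read counts. Covered shares of chromosomes used lengths from the file headers. The 2 Mb next to the centromere were taken at the high-coordinate end of X, 2L and 3L and at the low-coordinate end of 2R and 3R.

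The rule for the regions named in the text was fixed before the data were examined: the 10 widest and the 10 highest-scoring regions of the combined list, by coordinates alone where no annotation of the same genome release was to hand. Gene annotation of release 5 was not used here, and the gene table at hand is of release 6. For this reason the planned comparisons with genomic features, with transcription start sites and with lists of genes were not run, and no region is assigned to a gene. Alternatives were a requirement that 50% of the shorter region or 50% of each region overlap, the higher-scoring 50% or the highest-scoring 25% of each list, merging of regions closer than 500 bases, restriction to X, 2L, 2R, 3L, 3R and 4, and each replicate list in place of the combined list. Others were added after seeing the data, and the closing section names them. Circular shifts also gave chance values for the differences in score and width, for the overlap by width and for the combined list, and scores were ranked within 20 groups of like width. These were likewise added after seeing the data.

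Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used Matplotlib 3.10.9. The overlap test was tested on simulated data: all of the kept regions were found in 5 trials in which 60% of the 7177 regions of replicate 1 were kept in a copy, and 4% of 50 shifted copies of that list gave a p at or under 0.05. The median test called 100% of simulated sets of 2000 regions with a planted difference of 0.2, and 5% of sets without one. The simulated scores were drawn independently, unlike scores of neighbouring regions, and the shifted copies follow the same shifts as the test. These runs therefore check the code only.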

Results

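H3K4me1, a histone mark found in textbook accounts at enhancers and beside active promoters, was mapped in nuclei of wild-type third-instar larvae, the last larval stage of the fly. The data were 3 lists of regions: 1 from each of 2 ChIP samples and 1 combined list for the series. The 2 input samples entered only through the lists they served. There was a single group of ChIP samples, so the comparisons are between the replicates, between the replicates and the combined list, and between chromosomes. Read depth is unknown for all lists.

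H3K4me1-enriched regions covered a large part of the chromosome arms in these larvae. Replicate 1 held 7177 enriched regions spanning 35.1 Mb, and replicate 2 held 9903 spanning 39.1 Mb. Together X, 2L, 2R, 3L, 3R and 4 were covered to 30.8% ± 2.34 (SD, n = 2), with 29.1% in replicate 1 and 32.5% in replicate 2. The combined list held 9501 regions spanning 44.7 Mb, or 37.0% of these chromosomes. Region counts differed more between replicates (1.38-fold) than covered bases did (1.11-fold), and regions of replicate 2 were narrower, with a median width of 2599 bases against 3270. The narrowest region measured 1301 bases in both replicates and 1001 in the combined list. Broad regions of at least 10 kb numbered 738 in replicate 1 and 612 in replicate 2, and held 33.1% and 23.7% of the covered bases. The widest spanned 79.3 kb in replicate 1 (2R:8852119-8931460) and 50.9 kb in replicate 2 (X:2044365-2095275). Wider regions had higher scores, with a Spearman rho across regions of 0.82 in replicate 1 and 0.79 in replicate 2.

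The replicates marked largely the same sequence. Of the 7177 regions of replicate 1, 6467 (90.1%, 95% Wilson interval 89.4 to 90.8) overlapped a region of replicate 2. Of the 9903 regions of replicate 2, 7454 (75.3%, interval 74.4 to 76.1) overlapped a region of replicate 1. The lists shared 28.8 Mb, which was 63.2% of their union, 81.8% of the bases of replicate 1 and 73.5% of those of replicate 2. Every region of at least 10 kb, 738 in replicate 1 and 612 in replicate 2, was met by the other list, where circular shifts gave 66.3% and 61.6% on average. Of regions under 2 kb, 74.5% in replicate 1 and 47.2% in replicate 2 were met, where shifts gave 41.6% and 36.6%. After circular shifts of one list, 49.7% of replicate 1 regions, 42.6% of replicate 2 regions and 18.5% of the union were shared on average, and none of the 1000 shifts reached the observed values (one-sided permutation p from circular shifts = 0.001 for each, the smallest possible). When 50% of each region had to overlap, the shares were 56.1% and 40.7%, where shifts gave 12.4% and 8.96% on average. Between the highest-scoring 25% of each list the shared part of the union was 41.7%, where shifts gave 8.54%. In 1561 cases a single region of replicate 1 lay over 2 or more regions of replicate 2, and in 1012 cases the reverse.

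Regions seen in both replicates had higher median scores and widths than regions seen in one, by more than chance overlap of wide regions gave. In replicate 1 the median score was 0.71 for the 6467 overlapping regions and 0.50 for the other 710, a difference of 0.21. In replicate 2 it was 0.73 for 7454 regions and 0.47 for 2449, a difference of 0.26. Median widths were 3589 against 1878 bases in replicate 1 and 3270 against 1703 bases in replicate 2 (two-sided permutation p = 1e-05 for each of the 4 differences against no difference, the smallest possible). Wide regions meet another list more easily, and under circular shifts of the other list the mean differences were 0.07 in score and 922.1 bases in replicate 1, and 0.08 and 613.6 bases in replicate 2 (one-sided permutation p from circular shifts = 0.001 for each, the smallest possible). Among regions of like width the replicates went opposite ways. The median score percentile of overlapping regions was 51.3 against 39.8 for the others in replicate 1, a difference of 11.4 where 95% of shifts lay between -1.67 and 3.14. In replicate 2 it was 49.3 against 52.3, a difference of -3.03 where 95% of shifts lay between -1.82 and 2.32. With each list divided into 10 equal groups by score, the overlapping share of replicate 1 regions went from 71.0% in the lowest group to 99.6% in the highest. In replicate 2 it lay between 54.6% and 61.6% over the 5 lowest groups and reached 99.9% in the highest. Median width rose along these groups too, from 1679.5 to 9762.5 bases in replicate 1 and from 1596 to 7327 in replicate 2. The trend therefore cannot be credited to score apart from width. When 50% of each region had to overlap, the difference in median score in replicate 1 was 0.08, and the difference in median width there was 775.5 bases.

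**Figure D1:**
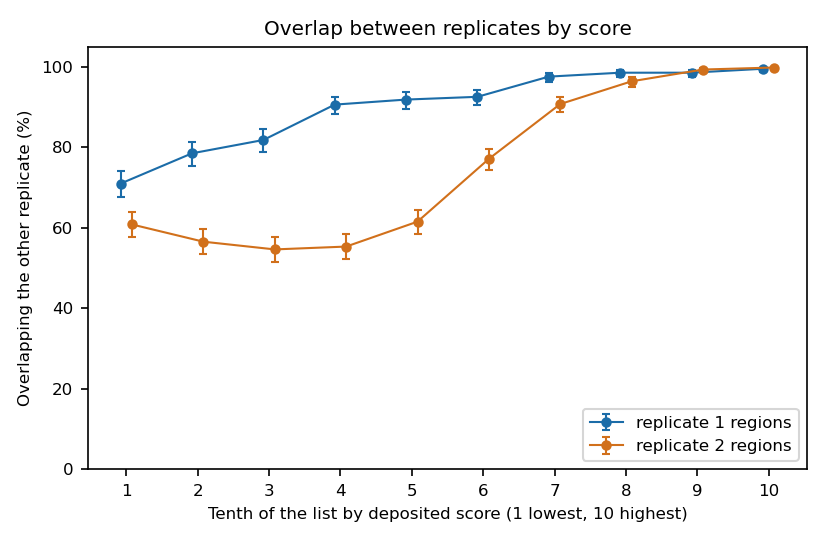
Percentage of enriched regions that overlapped the other replicate by at least 1 base (vertical axis) against 10 equal groups of the list by deposited score (horizontal axis, lowest to highest), for replicate 1 (blue) and replicate 2 (orange), with 95% Wilson intervals as bars. Nearly all regions of the highest group were shared (99.6% and 99.9%), while in replicate 2 the 5 lowest groups stayed between 54.6% and 61.6%. Median width also rose along the groups in both replicates, so the trend cannot be credited to score apart from width.

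Regions that matched one to one also ranked alike by score, with width not held constant. Across 3317 such pairs, the Spearman rho of the scores was 0.59 and that of the widths 0.65 (two-sided permutation p = 1e-05 for the scores, the smallest possible, across regions, which are not independent replicates). Scores followed width within each list (rho 0.82 and 0.79), so like widths alone would give some agreement in score. The p therefore does not speak for agreement in score beyond width. The pairs are only part of the 6467 and 7454 overlapping regions and leave out those split in the other list. Within single chromosomes the rho of the scores ranged from 0.55 on X to 0.64 on 2R, and was 0.48 over the 20 pairs on chromosome 4. Among the higher-scoring 50% of each list it was 0.32 over 1813 pairs.

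The combined list overlapped both replicates in 60.7% of its regions by at least 1 base. Of its 9501 regions, 5764 (95% Wilson interval 59.7 to 61.6%) overlapped regions of both replicates, and these held 85.4% of its bases. A further 728 regions met replicate 1 alone, 2201 met replicate 2 alone, and 808 (8.50%, interval 7.96 to 9.08) met neither. Under circular shifts of the combined list, 40.2% met both and 47.9% met neither on average. The combined list rests on the same 2 ChIP samples as the replicate lists, so its overlap with them is not independent agreement. Regions found in both had a median width of 4699.5 bases and a median score of 0.68, against 1186.5 bases and 0.33 for regions found in neither. Conversely, 97.1% of replicate 1 regions and 96.8% of replicate 2 regions overlapped the combined list. The combined list reached to narrower regions than the replicate lists: 1154 of its regions were under 1301 bases wide, and 567 of these met neither replicate. When 50% of each region had to overlap, 40.5% of combined regions, with 50.6% of its bases, met both replicates and 15.1% met neither.

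Enriched regions were spread over the 5 large chromosome arms and covered little of the small chromosome 4. Sequence to which reads cannot be assigned and a lower density of the mark cannot be told apart there, as the closing part sets out. A covered share about as low was found in the 2 Mb nearest the centromere of some large arms, given below. On the large arms the covered share ranged from 25.8% ± 0.931 (SD, n = 2) on 2L to 35.8% ± 4.15 on 2R, with 31.9% ± 2.47 on X, 29.7% ± 1.63 on 3L and 32.3% ± 2.96 on 3R. On chromosome 4 it was 7.63% ± 3.89, with 10.4% in replicate 1 and 4.88% in replicate 2, and both values lay below the lowest large-arm value of either replicate (25.1% on 2L). In the combined list the large arms were covered 4.91 times as densely as chromosome 4 (37.4% against 7.61%). The arm 2L lay below 2R in both replicates (25.1% and 26.4% against 32.9% and 38.7%). X was covered 1.04 times as much in replicate 1 and 1.03 times as much in replicate 2 as the 4 large autosomal arms pooled, but less than 2R in each replicate. X and 3R were nearly level, at 30.19% and 30.21% in replicate 1 and 33.7% and 34.4% in replicate 2. In the combined list X lay above 3R (39.0% against 38.7%). Broad regions of at least 10 kb were also unevenly placed: the combined list held 228 on 2R (10.8 per Mb), 157 on 2L (6.82 per Mb) and 0 on chromosome 4, where replicate 1 held 1 and replicate 2 held 0. No exact permutation test over 2 samples can reach 0.05, so these are values with their spread. The ratio of the large arms to chromosome 4 depended on the replicate, at 2.83 in replicate 1 and 6.71 in replicate 2, and was 9.30 for the higher-scoring 50% of the combined list. For combined regions found in both replicates, a setting chosen after seeing the data, chromosome 4 was covered to 4.50% and the ratio was 7.10.

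**Figure D2:**
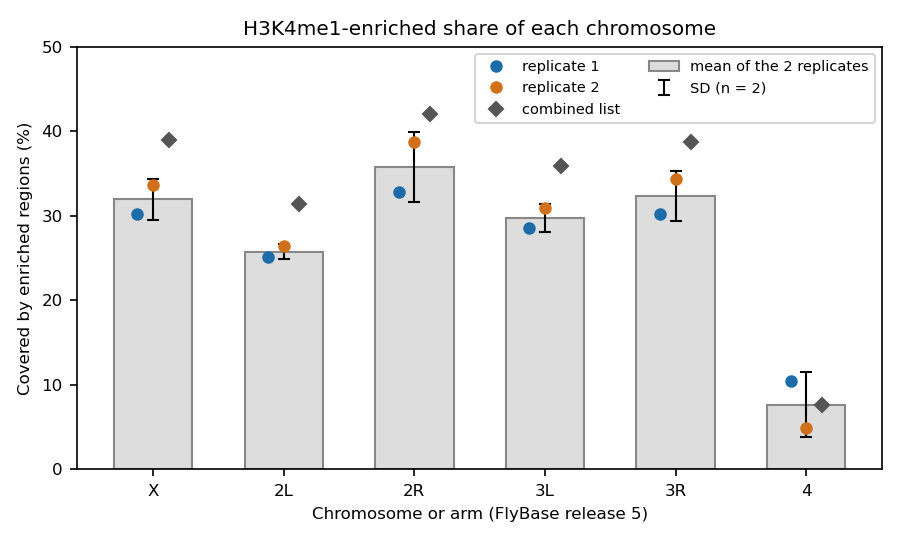
Percentage of each chromosome or arm covered by enriched regions (vertical axis), as the mean of the 2 replicates (grey bars) with SD (n = 2), the replicates themselves (blue and orange points) and the combined list (grey diamonds). Chromosome 4, at 10.4% and 4.88%, lay below all 5 large arms, and it was the only one of the 6 on which replicate 1 lay above replicate 2.

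Along the 5 large arms and chromosome 4, coverage varied between 0% and 63.3% of a 1 Mb window in the combined list, around a median of 38.8%. The densest windows were 2R:3000001-4000000 (50.4% in replicate 1 and 60.7% in replicate 2), 3L:1-1000000 (49.2% and 53.1%) and X:1000001-2000000 (46.0% and 58.4%). The sparsest were 3L:23000001-24000000 (0.131% and 0%), 2R:1-1000000 (1.16% and 0.289%) and 2L:22000001-23000000 (4.16% and 2.55%), which lie next to the centromere. Over the 5 large arms the 2 Mb nearest the centromere were covered to 14.1% and 14.4% in the replicates, against 30.8% and 34.5% for the rest. The arm 3R was the exception, with 35.4% and 39.6% in its 2 Mb nearest the centromere against 29.8% and 34.0% elsewhere. Some heterochromatin is on separate scaffolds, so the 2 Mb may not hold like sequence on each arm. Sequence to which reads cannot be assigned was not weighed for these windows, so low coverage there need not mean a low density of the mark. Window values of the replicates were closely related across 118 windows, of which 1 was on chromosome 4 (Spearman rho 0.94, two-sided permutation p = 1e-05, the smallest possible, across windows, which are not independent replicates), and replicate 2 was higher in 99 of them.

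**Figure D3:**
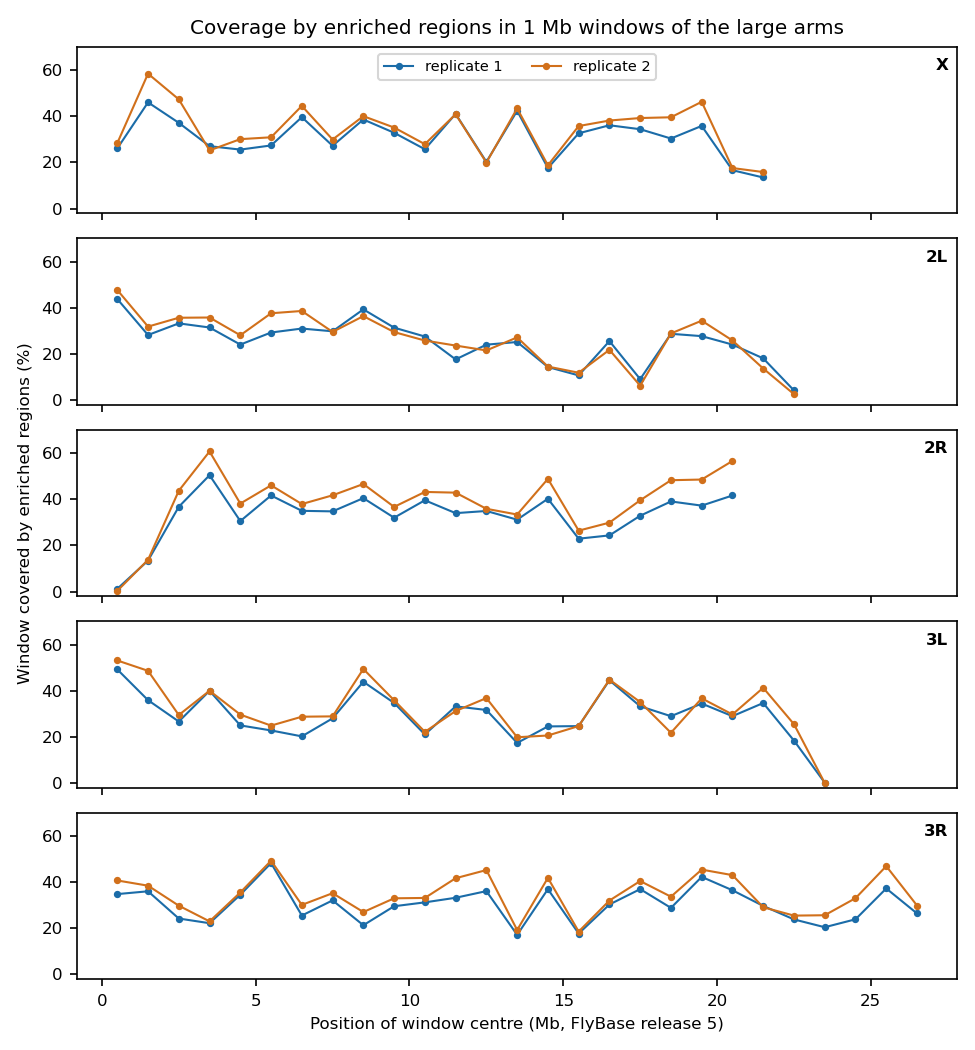
Percentage of each full 1 Mb window covered by enriched regions (vertical axis) along the 5 large arms (horizontal axis, Mb), for replicate 1 (blue) and replicate 2 (orange). Both replicates fall towards 0 at the high-coordinate end of 2L and 3L and the low-coordinate end of 2R, and peak at 50.4% and 60.7% in the window from 3 Mb on 2R.

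The 10 widest regions of the combined list were long domains that both replicates marked nearly throughout. Since the combined list rests on the same 2 ChIP samples, this is not independent agreement. They spanned 43.8 to 71.0 kb, had scores between 1.08 and 1.58, and were covered to between 84.9% and 100% by replicate 1 and between 91.6% and 99.8% by replicate 2. The widest, X:1451981-1522942, overlapped 6 regions of replicate 1, which covered 84.9% of it, and 2 regions of replicate 2, which covered 99.7%. It was followed by 2L:476199-539228 (63.0 kb), 3L:17954739-18017688 (63.0 kb), 3R:12023857-12086057 (62.2 kb) and 3R:25580350-25635449 (55.1 kb). The others were 2R:8882200-8931305, X:1747423-1794199, 3R:7027849-7072909, X:18135074-18180121 and 2R:7060822-7104579. None lay on chromosome 4, and 3 of the 10 lay on X.

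**Figure D4:**
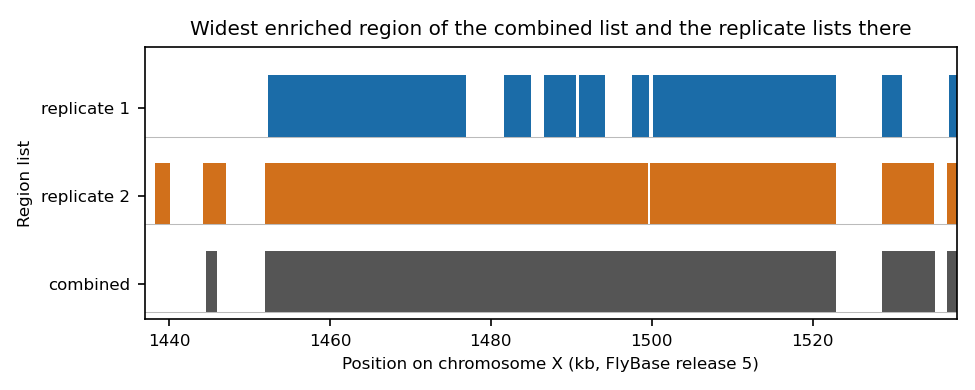
Enriched regions of replicate 1 (blue), replicate 2 (orange) and the combined list (grey) around X:1451981-1522942, against position in kb, with 1 bar per region and equal bar heights. The combined list has a single region of 71.0 kb where replicate 1 has 6 regions and replicate 2 has 2, which lie so close that their gap shows as a thin line.

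The 10 highest-scoring regions of the combined list fell into 2 kinds. Found in both replicates were 4 of them: X:2175006-2203906 (28.9 kb, score 1.78), X:1831750-1849772 (18.0 kb, 1.77), 3R:13520716-13543638 (22.9 kb, 1.67) and X:17681871-17686310 (4.44 kb, 1.66). The other 6 were between 1001 and 1015 bases wide and met no region of either replicate. Their scores ran from 1.78 at 3R:3534305-3535319 to 3.18 at both 2R:4289485-4290485 and X:10445349-10446349. In the replicate lists the highest-scoring regions were X:2175787-2203784 in replicate 1 (28.0 kb, score 1.90), of which replicate 2 covered 98.9%, and X:2019976-2026904 in replicate 2 (6.93 kb, score 2.13), of which replicate 1 covered 100%.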

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

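The tests of overlap and of distance to replicate 1 were set before their results were seen, and the tests of gap lengths were chosen after. Regions of depletion, with scores below 0, entered no comparison of the report and exceeded the 3 regions that a count of 0 allows: replicate 2 held 39 and the combined list 17. Replicate 1 held 0, but its lowest enriched score was 0.10, against 1.19e-06 in replicate 2, and where each list ended is not given in the sources used here.

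The 39 depleted regions of replicate 2 had a median width of 1628 bases and scores between -0.16 and -0.0018, close to no enrichment. There were 13 on 2L, 12 on 3R and 0 on chromosome 4. Of the 39, 7 met a depleted region of the combined list, among them 2R:15613327-15615046, 2L:10386386-10388247 and 3L:19971656-19973137, which were chosen after their values were seen. Enriched regions of replicate 1 covered 87.5%, 98.8% and 0% of the matching regions of replicate 2. The rest of the 7 were covered to 100% at 2R:13343494-13345320 and 3L:11244023-11245834, and to 0% at 2R:10532496-10534035 and X:17043388-17045106.

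A scatter of single sites without regard to enriched sequence was argued against: 29 of the 39 (74.4%) overlapped enriched regions of replicate 1, against a median of 35.9% and a central 95% range of 20.5% to 51.3% over 1000 circular shifts. The median distance to the nearest enriched region of replicate 1 was 0 bases, but the lower end of the shifted range was also 0, so that test decided nothing. In the list of replicate 2 itself, depleted and enriched regions overlapped in 0 cases, so lying between enriched regions was given by the list. Of the 39, 38 lay in a gap between 2 enriched regions. The median gap was 8603.5 bases long, against 51208 bases for random placement in gaps (one-sided permutation p over 1000 random placements = 0.001, the smallest possible). Of the 38 gaps, 8 were under 5 kb, where random placement gave 1.82 on average. Random placement falls mostly in long gaps, so these values alone decide nothing. With the same chance for every gap that could hold the region, the median was 5141 bases (95% range 3368 to 8320). The gaps were therefore short against random positions and long against typical gaps, so dips between neighbouring enriched regions stay open, and no biological explanation was tested because the design has a single group.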

How the results depend on the processing

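The shifts of 50 to 500 kb, the excess over circular shifts, the ranking of scores among regions of like width, the removal of the 2 Mb next to the centromere, the restriction to combined regions found in both replicates and the width minimum for combined regions were chosen after seeing the data. The overlap of the replicates, the score and width differences and the score correlation kept their direction in 43 of the 44 alternatives run. The exception was the score difference in replicate 2 among regions of like width, which was -3.03 percentile points, against 11.4 in replicate 1, and the cause was not tested. Every p of the 43 was the smallest its test can give, so only the sizes inform. Overlap ran from 56.1% to 90.4% for replicate 1 and from 40.7% to 75.7% for replicate 2. The shared union ran from 41.7% to 63.7% and rho from 0.32 to 0.67. The score difference ran from 0.08 to 0.22 in replicate 1 and from 0.26 to 0.28 in replicate 2. The score differences in excess of shifts were 0.14 and 0.18. With only the higher-scoring 50% of each list, which keeps fewer regions by construction, there were 3588, 4952 and 4750 regions spanning 26.2, 28.7 and 35.1 Mb in replicate 1, replicate 2 and the combined list. Chromosome 4 was then covered to 3.17%, the large arms 9.30 times as densely, and 59.6% of combined regions met both replicates and 6.84% neither. These 2 shares were 59.1% and 9.09% when 50% of the shorter region had to overlap and 40.5% and 15.1% when 50% of each region had to. After merging, 63.5% met both. The width minimum left 8347 combined regions over 43.3 Mb, and regions in both replicates gave 4.50% for chromosome 4 and a ratio of 7.10. Beyond the stricter construction of these settings, the cause was not tested. Replacing the combined list with a single replicate gave a range of 4.88% to 10.4% for chromosome 4 and of 2.83 to 6.71 for its ratio to the large arms. Of the other values without a test, covered shares of large arms moved beyond the replicate spread upward in 2 cases and downward in 19, median widths moved upward in 5, and 14 stayed within it.

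No paired analysis was possible because the inputs, which share replicate numbers with the ChIP samples, have no region lists here. The alternatives laid out before the data were examined for promoter windows, transcription start sites and gene lists were not run, since the annotation at hand is of another genome release. Unknown read depth limits any statement on narrow, low-scoring regions seen in 1 replicate.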

Other observations

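All tests in this part were chosen after the results were seen. A few enriched regions lay on sequence outside the chromosome arms, and only some of them were found in both replicates. The scaffolds assigned to heterochromatin held 15 regions in replicate 1 and 10 in replicate 2, and 9 of each overlapped the other. On XHet, 5 of 5 regions in each replicate overlapped, and the scaffold was covered to 7.34% and 5.94%, near the level of chromosome 4. On YHet each list held 1 region, at YHet:305764-307546 in replicate 1 and YHet:305589-307771 in replicate 2. On 2RHet replicate 1 held 3 regions and replicate 2 held 0, and on 3RHet the 2 regions of replicate 1 did not meet the 1 of replicate 2. Unplaced sequence (U) held 10 and 13 regions, of which 7 of each overlapped. Over all heterochromatic scaffolds the covered share was 0.426% and 0.239%.

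Chromosome 4 also differed between the replicates. Replicate 1 covered 140.4 kb of it and replicate 2 covered 66.0 kb, a ratio of 2.13, whereas on all 5 large arms replicate 1 covered less than replicate 2. Of the 52 regions of replicate 1 on chromosome 4, 21 overlapped replicate 2, and of the 32 regions of replicate 2 there, 22 overlapped replicate 1. The smaller covered length in replicate 2 leaves less for regions of replicate 1 to meet. No shift value is given for chromosome 4 alone, so these counts are descriptive. In large-arm windows of the same length, the ratio of replicate 1 to replicate 2 was 1.00 over the 9 sparsest windows and 0.894 over the other 77. Replicate 1 was higher in 5 of the 9 and in 9 of the 77 (Fisher's exact p = 0.00489, two-sided, across windows, which are not independent replicates). This p does not measure the spread between replicates. The highest ratio among windows covered to at least 1% in each replicate was 1.35. The ratio was at least that of chromosome 4 in 2 of the 86 windows, 3L:22981570-24333426 (0.222% and 0%) and 2R:1-1351857 (1.76% and 0.362%).

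For the low coverage of chromosome 4, its short length was weighed as the cause. At most 2.22% of 1124 overlapping large-arm windows of its length were covered as little, in either replicate. The windows overlap and chromosome 4 was singled out for its low value, so this share is descriptive and does not settle the question. Sequence to which reads cannot be assigned was weighed through the scores, because a ratio to input would stay at the level of other regions where sequence is merely missing. Regions on chromosome 4 had a median width-matched score percentile of 19.5 in replicate 1 (52 regions, two-sided permutation p = 1e-05, the smallest possible) and 35.1 in replicate 2 (32 regions, p = 0.0781 by the same permutation test). Both lie below 50, but the second did not pass the threshold, so unassignable sequence and a lower density of the mark cannot be told apart here. No biological explanation was tested.

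The 6 narrow regions at the top of the combined list belong to 10 regions that were narrower than any replicate region and in the top-scoring 10% of its regions. Only 1 of the 10 (10%) lay within 1 kb of a region of either replicate. Short enriched sites that the replicate lists missed only for their width would leave no region there either, so this value decides nothing and that explanation stays open. Leaving out the 2 regions that set the highest score, 6 of 8 (75%) had scores at a log2 ratio of whole numbers up to 60 from it, within 1e-06, against 3 of 939 (0.319%) regions of the same score range found in both replicates (Fisher's exact p = 2.37e-12, two-sided). The score of 2.66 at 3L:22616279-22617280, for example, differed from 3.18 by the log2 of 10/7. These scores may therefore be ratios of few reads, which would not exclude enrichment at these sites.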
